A study of Mus musculus with 2 samples.

How the data were processed

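Chromatin immunoprecipitation of CTCF, the zinc-finger protein that marks many chromatin loop anchors, followed by sequencing was carried out in 2 mouse samples: E14 embryonic stem cells (ESC), a line kept undifferentiated with leukemia inhibitory factor, and neural precursor cells (NPC) derived from the same E14 line and grown with basic FGF and EGF. Both samples used the same anti-CTCF antibody, and libraries were sequenced on the SOLiD platform, per the labels' protocols. Each cell type was represented by 1 library, so the spread between cultures is unknown, no test between cell types was made and no p-value is given.

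The authors deposited 1 peak list per library. Peaks were called with MACS on each library separately, per the file headers, and coordinates are on mm9, per the submitters' processing notes. The MACS version, the calling threshold, the aligner and the control used are not given in the sources used here. The track name in both files ends in CONTROL, a suffix that the files do not explain and that was not interpreted here; the lists were taken as CTCF peaks, per the labels. Every peak has a start, an end and a score, and the score is the value the authors deposited for that peak; its definition is not stated in the files. All scores were at least 100.0, and scores piled up at 3100, which 173 ESC peaks and 208 NPC peaks had exactly. Score levels were compared only within a list; between the lists, scores were related only by correlation and by within-list percentiles at paired sites, and by following sites chosen by ESC score in the NPC list. The lists hold no read counts, summits, strand or fold enrichment, so the sequencing depth behind each list is unknown, and a deeper or cleaner library would be expected to yield more weak peaks. The ESC peak numbers run to 54157, and 6 of those numbers are absent from the list; these peaks were not analysed here.

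Overlap between the lists was computed with bedtools 2.31.1. A peak was called shared when it overlapped a peak of the other list by at least 1 bp, and ESC-only or NPC-only otherwise. Shares are given with exact Clopper-Pearson 95% intervals, which treat peaks as independent and cover counting error only. The overlap expected by chance was taken from 100 circular shifts of the NPC list within each chromosome. Each list was also divided by score into 10 bins of equal size. Scores of the 1-to-1 overlapping peaks were compared by Spearman and Pearson (log10) correlation across peaks, which are not replicates. Medians carry distribution-free 95% intervals from order statistics.

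For each chromosome the share of unshared peaks and the median score were computed. Cell-type-only peaks were then counted by peak centre in windows of 1 Mb and set beside 100 random reassignments of the class labels among peaks of the same chromosome. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used, with matplotlib 3.10.9 for plots. The overlap step was tested on simulated data made from the 54151 ESC peaks: all 40000 planted shared sites were found (100.0%), and 0.212% of the other sites were called shared. The planted sites were ESC peaks moved by at most 100 bp, and the narrowest ESC peak was 127 bp, so all had to be found. That simulation checked the code only and does not address sites missed at the calling limit. The step that counts runs of neighbouring cell-type-only peaks was tested on the same peaks: with randomly placed labels the run share was 25.6%, under the 26.5% reached by the highest of 100 shuffles, and with 3000 planted pairs it was 41.5%, against 34.6% for the highest shuffle.

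The peaks named in the text follow a rule set before the data were examined: for each cell type the 10 cell-type-only peaks with the highest score lying over 1 kb from any peak of the other list, the 5 shared peaks with the best worse-of-both rank, and the 3 windows of 1 Mb with most cell-type-only peaks per list. Alternatives fixed at the same time were a 50% reciprocal overlap, peak centres within 100 bp, peaks within 1 kb, the upper 50% of each list by score (against the same part or against the whole of the other list), lists of equal length, exclusion of the sex chromosomes and windows of 500 kb. Added after seeing the data were exclusion of chromosomes 15 and 5, shuffles and expected shares matched on score bin, and percentiles at shared sites weighted by score bin. No mm9 sequence or gene positions were used here. The planned comparisons of peaks with genes, with 11 gene lists, with the CTCF motif and with motif orientation were therefore not made, and peaks are named by position only.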

Results

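The data were 2 lists of CTCF-bound regions on mm9, 1 from E14 embryonic stem cells and 1 from neural precursor cells derived from them. The question the comparison addresses is which CTCF sites are occupied in each cell type; the series sets this beside chromatin looping, which was not analysed here. The ESC list held 54151 peaks covering 31.4 Mb, and the NPC list held 51421 peaks covering 22.8 Mb. ESC peaks were wider, with a median of 573 bp (interquartile range 465 to 683), against 433 bp (346 to 527) in NPC. The median peak score, as the authors gave it, was 517 in the ESC list and 385 in the NPC list. These levels describe each list and were not compared, because the score is not defined. There was 1 library per cell type, so each difference below is between these libraries and has no replicate check, and the intervals cover counting error over peaks only.

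Most CTCF sites were found in both cell types. Of the ESC peaks, 40062 (74.0%, 95% interval 73.6 to 74.4) overlapped an NPC peak, and of the NPC peaks, 40437 (78.6%, 78.3 to 79.0) overlapped an ESC peak. The remaining 14089 ESC peaks and 10984 NPC peaks had no overlap. Circular shifts of the NPC list gave a mean overlap of 2.09% of ESC peaks and at most 2.33% in 100 shifts, and a mean of 2.21% and at most 2.46% of NPC peaks. The 39595 pairs that matched 1-to-1 had centres a median of 32 bp apart. A further 407 ESC peaks spanned 2 or more NPC peaks, whereas 37 NPC peaks spanned 2 or more ESC peaks.

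Sharing was more frequent among peaks with higher scores. In the ESC list 33.2% (31.9 to 34.5) of the peaks in the lowest of 10 score bins were shared, against 99.5% (99.2 to 99.6) in the highest bin. The NPC list went from 45.6% (44.2 to 47.0) to 99.6% (99.4 to 99.8). ESC-only peaks had a median score of 193 (190 to 196) against 743 (734 to 750) for shared ESC peaks, and NPC-only peaks had a median of 168 (165 to 169) against 522 (516 to 530) for shared NPC peaks. Only 1342 ESC-only peaks (9.53% of them) and 1288 NPC-only peaks (11.7%) scored above the median of their own list. With the upper 50% of each list compared against the whole other list, 95.0% of ESC peaks and 95.0% of NPC peaks were shared.

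**Figure D1:**
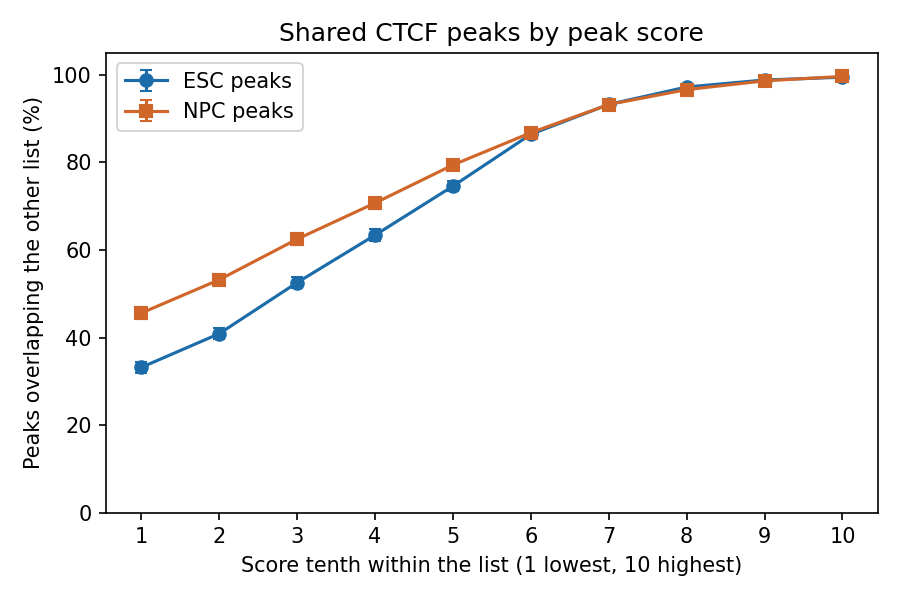
Share of CTCF peaks that overlap the other list by at least 1 bp (y axis, percent) against the score bin within each list (x axis, 10 bins of equal size from lowest to highest). Points are shares and bars are exact 95% intervals; both cell types climb from below 50% to above 99%.

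Sites that scored high in ESC tended to score high in NPC. Across the 39595 pairs Spearman's rho was 0.62 and Pearson's r of the log10 scores was 0.60; these are correlations across peaks within 2 libraries. The 5 shared peaks with the best ranks in both lists lay on chromosome 19 (ESC peak 47956786 to 47957605, score 3158), chromosome 4 (3894526 to 3895340, score 3152), chromosome 5 (122055951 to 122056921, score 3230), chromosome 8 (128473822 to 128474747, score 3126) and chromosome 1 (37476094 to 37476861, score 3199). Both peaks of each pair scored at least 3100. The NPC peak of the chromosome 1 pair was at 3100, a value it shared with other NPC peaks, so that its place among them is arbitrary. Of the 222 ESC and 255 NPC peaks at or above 3100, 173 and 208 were at exactly 3100. Why scores piled up there is not known, so peaks above 3100 may not be stronger than those at it. The choice of these 5 pairs therefore follows the order of the scores only.

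Some chromosomes recurred among the strongest cell-type-only peaks. The 10 ESC-only peaks with the highest scores reached between 1823 and 2801. They included 3 on chromosome 18 (2.90% of all ESC peaks), 2 on chromosome 5 (7.39%) and 2 on chromosome 12 (3.95%). The first lay at 37089402 to 37090814 on chromosome 18, was 1413 bp wide, scored 2801 (rank 348 of the ESC list) and was 7734 bp from the nearest NPC peak. The second lay on chromosome 12 at 18141938 to 18142644, scored 2591 and had no NPC peak within 49029 bp. The other chromosome 18 peaks were at 37890192 to 37890828 (score 2057) and 37839556 to 37840282 (score 1860). All 3 peaks of chromosome 18 lay between 37 and 38 Mb, so they form a local group. The chromosome 5 peaks were at 151904564 to 151905363 (score 1929) and 151205283 to 151206251 (score 1900), and the second peak of chromosome 12 was at 81840230 to 81840929 (score 1880). Single peaks on chromosome 17 (30758272 to 30758939, score 2051), chromosome 7 (97040152 to 97041070, score 1964) and chromosome 4 (86533493 to 86534338, score 1823) completed the list.

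The 10 strongest NPC-only peaks scored between 1524 and 2046, and chromosome 15, with 5.24% of all NPC peaks, held 4 of them. These lay at 88829509 to 88830020 (score 2005, 44767 bp from the nearest ESC peak), 65424428 to 65425121 (score 1908, 43780 bp away), 84630366 to 84631093 (score 1703) and 81911588 to 81912049 (score 1531). The strongest NPC-only peak was on chromosome 11 at 106150525 to 106151125, with a score of 2046 and an ESC peak 12213 bp away. The others were single peaks on chromosome 2 (24954389 to 24954945, score 1588), chromosome 1 (137028904 to 137029547, score 1587), chromosome 8 (32570749 to 32571235, score 1579), chromosome 4 (133330409 to 133331036, score 1557) and chromosome 14 (31463977 to 31464526, score 1524).

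Chromosome 15 departed from all other chromosomes. It held 2692 NPC peaks and 2209 ESC peaks, the only chromosome with more NPC than ESC peaks, while the whole NPC list was 95.0% as long as the ESC list. Of the NPC peaks on chromosome 15, 816 (30.3%, 28.6 to 32.1) had no ESC peak, against 18.5% to 24.0% on the other 18 autosomes. Of the ESC peaks on chromosome 15, 352 (15.9%, 14.4 to 17.5) had no NPC peak, against 24.1% to 30.3% elsewhere among the autosomes. At the 1-to-1 shared sites, the median within-list score percentile on chromosome 15 was 63.0 (60.1 to 65.8) in NPC, above the 46.5 to 54.0 of the other autosomes, and 44.8 (42.6 to 47.4) in ESC, below their 48.3 to 55.1. These percentiles depend on which peaks were paired: with pairs weighted to the pairing rate of their score bin, added after seeing the data, they were 56.5 (54.2 to 59.3) in NPC, against 46.1 to 54.4 on the other autosomes, and 50.4 (48.1 to 52.9) in ESC, inside their 47.3 to 53.5. All 11 segments of 10 Mb on this chromosome had a share of NPC-only peaks, from 20.9% to 42.5%, at or above the 20.9% of the rest of the NPC list. The interval included the share of the rest from 10 to 20 Mb (24.6%, 17.1 to 33.4), from 40 to 50 Mb (20.9%, 13.1 to 30.7) and from 100 to 110 Mb (25.6%, 20.2 to 31.6). In the upper 50% of the NPC list by score, 8.34% (6.95 to 9.91) of the peaks on chromosome 15 had no ESC peak, against 3.26% to 6.65% on the other autosomes.

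**Figure D2:**
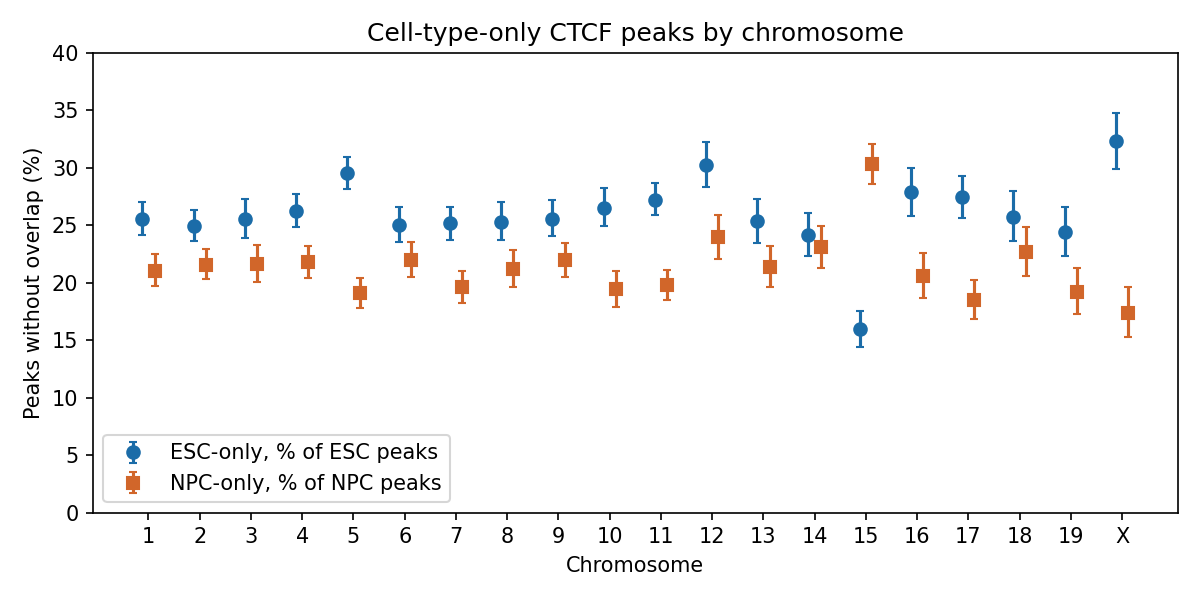
Share of peaks without overlap in the other list (y axis, percent) for chromosomes 1 to 19 and X (x axis), with exact 95% intervals. ESC-only shares lie above NPC-only shares except on chromosome 15, where they are 15.9% and 30.3%.

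**Figure D3:**
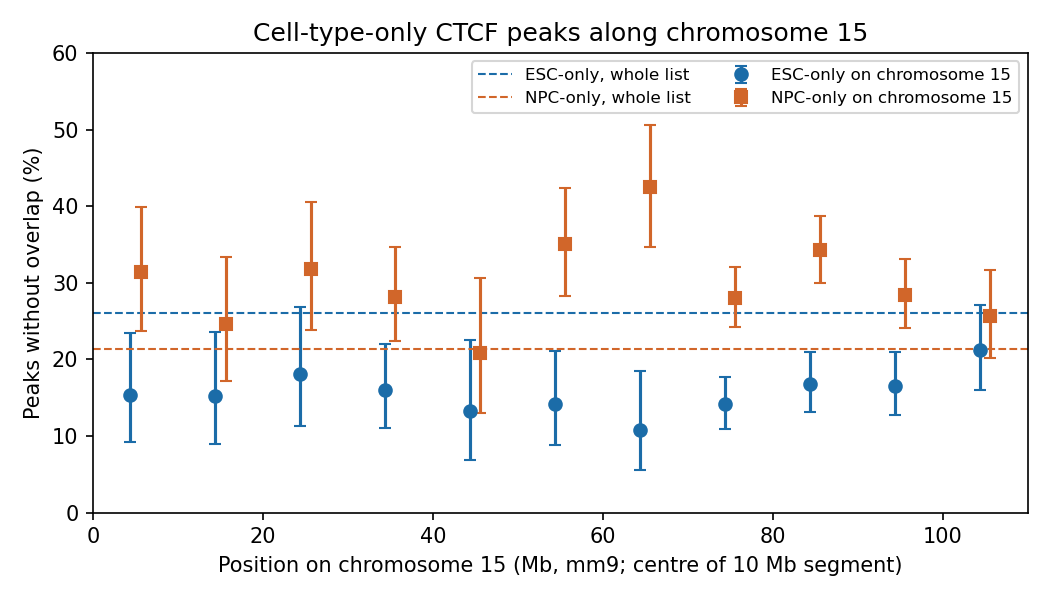
Share of peaks without overlap (y axis, percent) in 11 segments of 10 Mb along chromosome 15 (x axis, Mb on mm9), with exact 95% intervals; dashed lines are the shares over each whole list. The NPC-only share is highest, 42.5%, in the segment from 60 to 70 Mb.

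Chromosomes 5, 12 and X had the largest shares of ESC peaks without an NPC peak, apart from the 3 peaks of chromosome Y. On chromosome 5, 1182 of 4002 ESC peaks (29.5%, 28.1 to 31.0) had no NPC peak, and on chromosome 12, 648 of 2140 (30.3%, 28.3 to 32.3), compared with 26.0% in the whole list. The excess was not spread evenly over either chromosome. On chromosome 12 the ESC-only share was 46.3% (40.1 to 52.6) from 70 to 80 Mb. From 100 to 110 Mb it was 20.2% (15.6 to 25.4). On chromosome 5 it was 35.9% (31.6 to 40.4) from 110 to 120 Mb and 35.3% (31.5 to 39.3) from 120 to 130 Mb. From 30 to 40 Mb it was 20.9% (16.6 to 25.7), and from 130 to 140 Mb 25.9% (22.1 to 29.9). Of the NPC peaks on chromosome 12, 24.0% (22.1 to 25.9) had no ESC peak, the highest share among the autosomes except 15. From their scores alone 22.5% would be unshared, which lies inside that interval. For ESC peaks on chromosome 12 the share from scores alone was 26.6%, below the observed interval. On chromosome 5, 19.1% (17.8 to 20.4) of NPC peaks had no ESC peak. On chromosome X, 32.3% (29.9 to 34.7) of ESC peaks had no NPC peak, whereas 17.4% (15.3 to 19.6) of NPC peaks there had no ESC peak. Peaks on chromosome X scored low in both lists, with a median of 323 (308 to 342) against 529 (522 to 537) on the autosomes in ESC, and 264 (251 to 278) against 392 (385 to 397) in NPC. From those scores alone 35.5% of its ESC peaks and 27.6% of its NPC peaks would be unshared. Chromosome Y held 3 ESC peaks and no NPC peak.

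Cell-type-only peaks were unevenly spread within chromosomes. More ESC-only peaks than in any of 100 label shuffles were found in 59 of 2538 windows of 1 Mb, where a shuffle itself held 13.4 such windows on average; for NPC-only peaks there were 64 of 2514 windows, against 12.4. The windows with most ESC-only peaks were chromosome 5 from 148 to 149 Mb (45 of 83 ESC peaks, 54.2%, 42.9 to 65.2), chromosome 5 from 127 to 128 Mb (41 of 62, 66.1%, 53.0 to 77.7) and chromosome 18 from 37 to 38 Mb (39 of 87, 44.8%, 34.1 to 55.9). The NPC list had 43, 22 and 48 peaks in these windows, of which 5, 1 and 1 were NPC-only. The windows with most NPC-only peaks were chromosome 11 from 119 to 120 Mb (27 of 64 NPC peaks, 42.2%, 29.9 to 55.2), chromosome 11 from 117 to 118 Mb (26 of 73, 35.6%, 24.7 to 47.7) and chromosome 4 from 107 to 108 Mb (26 of 53, 49.1%, 35.1 to 63.2). These windows were picked for their counts, and in the shuffles the highest count in any window was 42 for ESC and 40 for NPC, so only the first ESC window passed it. The excess over the shuffle mean was 20.85, 22.73 and 17.5 peaks in the ESC windows, against at most 15.9 in any window of the shuffles, but 14.5, 11.83 and 14.26 peaks in the NPC windows, below the 15.15 reached there. With shuffles matched on score bin, added after seeing the data, it was 14.37, 8.61 and 12.52 peaks in the NPC windows, against at most 11.95. With the upper 50% of each list by score, the counts of such windows fell to 24 for ESC, where a shuffle held 9.68, and to 15 for NPC, where it held 9.51.

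The chromosome 18 window stood apart by the strength of its ESC-only peaks. Their median score was 655, against 193 over all ESC-only peaks, and 21 of the 39 scored above the median of the ESC list. Peaks were also dense there, with neighbouring ESC peak centres a median of 4795 bp apart against 17945 bp over the list. The density was not particular to this window, which was picked for its count of ESC-only peaks. It held 87 ESC peaks, against 83 on chromosome 5 from 148 to 149 Mb and 85 on chromosome 11 from 97 to 98 Mb. At the 46 sites of the window that matched 1-to-1, the median score percentile was 76.6 within ESC and 37.4 within NPC, and 39 of the 46 had a lower percentile in NPC. The clustered protocadherin genes, which encode adhesion proteins of neurons and are known CTCF targets, lie on mouse chromosome 18; gene positions on mm9 were not used here, and these peaks were not assigned to genes.

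**Figure D4:**
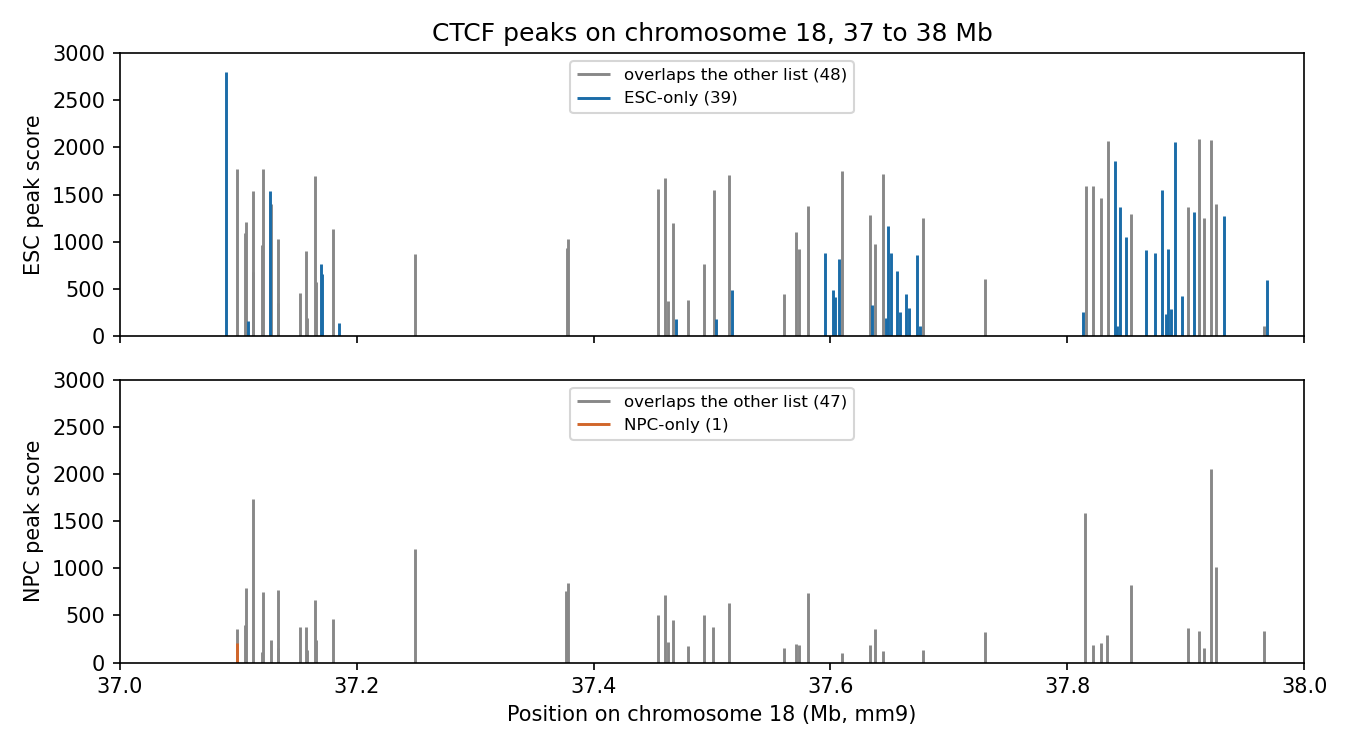
CTCF peaks on chromosome 18 from 37 to 38 Mb (x axis, mm9) in ESC (upper panel) and NPC (lower panel); each line is a peak, its height is the score within that list (y axis), and colour separates peaks that overlap the other list from those that do not. Of the 87 ESC peaks 39 are ESC-only, and of the 48 NPC peaks 1 is NPC-only.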

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

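The lists give no depth, so a missing overlap may be a site below the calling limit: from the lowest to the highest score bin the shared part of ESC peaks went from 33.2% to 99.5%, and with the upper 50% of each list against the whole other list 95.0% of ESC and 95.0% of NPC peaks were shared, leaving 1342 ESC-only and 1288 NPC-only peaks. The shared percentages of ESC and NPC peaks were 68.3% and 71.9% with 50% reciprocal overlap, 69.7% and 73.4% with centres within 100 bp, 76.0% and 80.3% with peaks within 1 kb, 72.8% and 77.2% with the upper 50% of both lists (7374 and 5871 peaks unshared), 76.3% and 77.0% with lists of equal length, and, chosen after seeing the data, 73.6% and 79.1% without chromosome 15. Unshared counts under the settings that kept both lists nearly whole stayed within 1.5 times of 14089 and 10984, and without the sex chromosomes or without chromosome 5 the shared percentages stayed inside their intervals; scores, correlation and windows were not recomputed under those exclusions. The median score of shared peaks was 723 in ESC and 507 in NPC with peaks within 1 kb, and the rank correlation was 0.66 with 50% reciprocal overlap. In the upper 50% of each list against the whole other list, the unshared shares of ESC peaks on chromosomes 15, 5 and X fell to 1.69%, 6.95% and 6.63%, and those of NPC peaks to 8.34%, 4.32% and 4.79%; chromosome 15 still had the lowest ESC share and the highest NPC share of the 19 autosomes, although its NPC interval (6.95 to 9.91) overlapped those of chromosome 8 (5.37 to 8.12) and chromosome 13 (5.06 to 8.29), and its ESC interval (1.02 to 2.63) overlapped that of chromosome 13 (1.99 to 4.16). Shares expected from the score bins alone, an alternative added after seeing the data, were 25.8%, 25.2% and 35.5% for ESC and 20.4%, 22.1% and 27.6% for NPC on the same 3 chromosomes. Windows above every shuffle numbered 24 for ESC and 15 for NPC in the upper 50%. The counts with windows of 500 kb (55 and 66) and with shuffles matched on score bin (46 and 54) stayed within 1.5 times of 59 and 64. A shuffle itself held 13.4 and 12.4 such windows in the main setting and 11.4 and 11.5 with matching. At 500 kb it held 19.5 and 20.0, of 4830 and 4766 windows, so relative to the shuffles the excess was smaller there. Settings foreseen for gene position, gene lists, the CTCF motif and motif orientation were not run, because no mm9 sequence or gene positions were used. With 1 library per cell type, no library could be left out.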

Other observations

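Among the tests below, the share of runs over all neighbours and over 50 kb, and the median score of all NPC peaks on chromosome 15, were set before their values were seen; the other tests, and the choice of segments in the next paragraph, came after the data had been seen.

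Segments of 10 Mb away from chromosome 15 also held large unshared shares. Among segments with at least 100 peaks, the largest ESC-only share was on chromosome 12 from 70 to 80 Mb, where 120 of 259 ESC peaks (46.3%, 40.1 to 52.6) had no NPC peak while 21 of 161 NPC peaks (13.0%, 8.26 to 19.2) had no ESC peak. On chromosome 6 from 60 to 70 Mb the counts were 56 of 144 ESC peaks (38.9%, 30.9 to 47.4) and 17 NPC peaks without an ESC peak (16.2%, 9.72 to 24.7), and on chromosome X from 50 to 60 Mb they were 39 of 107 (36.4%, 27.4 to 46.3) and 10 of 78 (12.8%, 6.32 to 22.3). For ESC peaks the chromosome X segment was near the 32.3% of that whole chromosome and the 35.5% expected there from scores alone. The largest NPC-only share was on chromosome 4 from 100 to 110 Mb, with 123 of 320 NPC peaks (38.4%, 33.1 to 44.0) and 43 of 239 ESC peaks (17.99%, 13.3 to 23.5) unshared. The next were chromosome 14 from 110 to 120 Mb, with 38 of 108 NPC peaks (35.2%, 26.2 to 45.0) and 23 of 93 ESC peaks (24.7%, 16.4 to 34.8), and chromosome 6 from 100 to 110 Mb, with 38 of 113 (33.6%, 25.01 to 43.1) and 35 of 110 (31.8%, 23.3 to 41.4). In these last segments the intervals of the cell types overlapped. NPC peaks also scored low there, with medians of 266 on chromosome 14 and 292 on chromosome 6, against 385 in the NPC list. The share expected from scores was not computed for these segments, so weak peaks may account for their NPC-only shares.

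A general difference in depth or calling limit is argued against as the whole cause of the excess of NPC-only peaks on chromosome 15, since it would act alike on peaks of the same score: from the scores of its NPC peaks 20.4% would be unshared, against 30.3% observed, with a lower limit of 28.6%. A few dense regions are argued against as the whole cause too, because 11 of 11 segments lay above the rest of the list. In the segments from 10 to 20, 40 to 50 and 100 to 110 Mb, however, the interval included the 20.9% of the rest. At the sites of the upper 50% of the ESC list, the median NPC score on chromosome 15 was 1217 (1162 to 1303), against 621 to 827 on the other autosomes, and 10 of 11 segments lay above the other autosomes together, which meets a bound written afterwards for a difference in copy number, but this repeats what the shared sites had already shown, so it does not decide whether the copy number of chromosome 15 differed between the cultures. With loss of 50% of the copies throughout the ESC culture, the median score of all ESC peaks there would be low. It was 534 (495 to 563), inside the 478 to 570 of the other autosomes and far from the 323 of chromosome X. This does not decide against the loss, because weak peaks drop out of a list at its calling limit. In NPC the same kind of median also stayed inside the range, while the scores at the sites chosen by ESC score did not. The ESC percentile at shared sites was low, 44.8, but more of the ESC peaks there were paired. With pairs weighted to the pairing rate of their score bin, an alternative added after seeing the data, it was 50.4 (48.1 to 52.9). The other autosomes had 47.3 to 53.5. As the weights draw on the scores of the same ESC peaks, the weighted value is not a separate check on the loss. Extra copies in NPC were not decided: the median score of all NPC peaks there, 427 (391 to 463), lay within the 353 to 437 of the other autosomes with an interval that reached above them, and it was above the other autosomes in only 6 of 11 segments, fewer than predicted beforehand for extra copies. Different CTCF binding along the whole chromosome between the cell types stays open too and was not tested, as no counts of input DNA were analysed.

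The 39 ESC-only peaks on chromosome 18 from 37 to 38 Mb were set beside 100 shuffles matched on chromosome and score bin, which gave a mean of 14.03 in this window. Since the window was chosen for its count, the fair comparison is with the whole list: the highest count in any window was 37 in the matched shuffles and 42 in shuffles within chromosomes only, and the excess over the mean was 24.97 here against at most 12.1 in any window of the matched shuffles. This argues against a general difference in depth or calling limit. Loss of all copies of the window in NPC is argued against by the 48 NPC peaks called there, 5 of them in the top 25% of NPC scores. A partial loss of DNA and lower CTCF occupancy in NPC stay open, and the cell type, which the design names, was not separated from them.

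ESC-only peaks tended to follow each other along the chromosomes. The next ESC peak was also ESC-only for 31.7% (30.9 to 32.5) of them, against 27.0% on average and at most 27.6% in 100 shuffles matched on chromosome and score bin, so score and chromosome alone do not account for it. The excess in ESC fell with distance: the share was 33.3% against at most 26.7% up to 10 kb apart, 31.4% against at most 28.1% over 10 kb and up to 50 kb apart, and 29.7% against at most 30.5% over 50 kb apart. The absence of an excess over 50 kb is what had been predicted beforehand if calls of 1 site split into several were the cause, and up to 10 kb apart such calls remain possible. As the whole cause they are argued against by the excess between 10 kb and 50 kb apart, a range chosen afterwards, when the widest ESC peak was 3293 bp, and by NPC, where the share over 50 kb apart was 29.8% against at most 25.9%. In NPC it was 28.2% against at most 23.5% over all neighbours, 28.3% against at most 22.8% up to 10 kb apart and 27.1% against at most 23.99% over 10 kb and up to 50 kb apart. Regional changes in occupancy and regional differences in copy number both remain open as hypotheses.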
